A study of Tigriopus californicus with 9 samples.

How the data were processed

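The series measured polyA RNA by sequencing in 9 libraries of the copepod Tigriopus californicus, each from a pool of 400 to 500 animals of all stages kept at 20 °C for 2 h before lysis. The titles place 3 libraries in the San Diego population (SD), 2 in the Santa Cruz population (SCN), 2 in hybrids with SD mothers (SDf x SCNm) and 2 in hybrids with SCN mothers (SCNf x SDm). Hybrids had been bred to the third hybrid generation. For both SCNf x SDm libraries the source label names the opposite cross, and the titles were used. Per the labels' protocols, SD replicate 1 and SCN replicate 1 shared sequencing run 1, SD replicate 2 had run 2, SD replicate 3 and SCN replicate 2 shared run 3, SDf x SCNm replicate 1 had run 4, and the other 3 hybrid libraries shared run 5. Parents and hybrids therefore never shared a run. The run 3 libraries were first registered under a different project.

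The deposited values are RPKM, reads per kilobase of contig per M reads, per the file headers. Each of 13758 features pairs an SD contig with an SCN contig, or is 1 of 13 mitochondrial genes, and carries a predicted protein name where one was given. The aligner, the counting method, any filter and the population whose contigs each library was aligned to are not given in the sources used here. Contigs are named below by the SD identifier without its prefix. No contig identifier matched the gene table of the Tcal_SD_v2.1 assembly, so gene names come from the deposited files alone and no genome coordinates are given. A total of 3811 features had no name and 8985 had an informative one. Placeholder names, such as hypothetical or uncharacterized protein, were set apart as uninformative after values had been looked at.

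Low RPKM values in each library fell on evenly spaced steps, and a contig's step had the same relation to depth in all 9 libraries. Whole reads could be recovered from these steps for 13690 of 13758 features (99.5%), and 99.4% of values lay within 0.05 read of a whole number. The deposited values also hold an added constant of 1.12 to 18.4 reads, depending on the library, so that no feature is at 0. On simulated data the recovery returned 99.7% of features, with 100% of their values exact. These reads gave each library's depth and fed alternatives only.

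The main test was limma (version 3.58.1, R 4.3.3) on log2(RPKM + 1) with a mean-variance trend, fitted to all 9 libraries with 4 group means, so that groups of 2 or 3 libraries share 1 estimate of the spread. Fold changes are on that log2(RPKM + 1) scale, which understates changes of low features. The Benjamini-Hochberg adjusted p was taken against 0.05 over all features of a comparison. The planned filter, a mean RPKM of at least 1, removed 0 features. The comparisons were SD against SCN, hybrids against the midparent (the mean of the SD and SCN means on the log2 scale), hybrids against each parent, each cross against the midparent, and SDf x SCNm against SCNf x SDm. Transgressive features are those past the threshold in the same direction against both parents. On simulated data with 200 features changed by known amounts, the hybrids against midparent test called 12%, 88%, 100% and 100% of changes of log2 1, 2, 3 and 4, and 10 unchanged features. SD against SCN called 8%, 54%, 92% and 98% of them, with 4 unchanged features. The comparison of the crosses called 2%, 40%, 90% and 96%, with 8 unchanged features.

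A fixed set of 24 gene lists was matched on protein names, and 22 lists with at least 5 members were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry, adjusted over the lists of a comparison. Camera compares a list's members with all other features, and fry tests them against no change. The lists were mtDNA-encoded OXPHOS genes, nuclear OXPHOS complexes I to V, mitochondrial ribosomal proteins, mtDNA transcription and replication, cytosolic ribosomal proteins, heat shock proteins and chaperones, antioxidant and glutathione genes, cytochrome P450, glycolysis and the TCA cycle, cuticle and chitin, digestive peptidases, proteasome and ubiquitin, immune recognition, and oxygen transport. Markers of stage, sex and tissue were yolk, sperm and cilia, germline, cell division and histones, muscle, and the nervous system. Another 3 lists (all nuclear OXPHOS genes, F-type ATP synthase and V-type ATPase) were added after the names had been seen. Lists match words, so a few members belong elsewhere, such as a ribosomal protein kinase among the ribosomal proteins. The pattern of the mtDNA transcription and replication list (5 members) also takes mitochondrial tRNA charging enzymes. TFAM was added to that list by its contig identifier. Near-identical family members, cuticle proteins and P450s among them, can share reads, and how such reads were counted is not given in the sources used here.

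Groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes, for the main comparisons, the 8 named features with the largest change in each direction among those past the threshold whose libraries all differ the same way, up to 3 members of each list by p-value, and all mitochondrial genes; where fewer than 8 pass, those with the smallest p are given as not passing. For unnamed features at most 2 per direction are given. Alternatives fixed with these were pseudocounts of 0.1 and 5, a minimum mean RPKM of 5, quantile normalization, median-of-ratios scaling, array weights, the replicate number as a block, the sequencing run as a block, 2 groups in place of 4, and each library left out in turn. After the data had been seen, limma voom on recovered reads, removal of the added constant, libraries thinned to 1 depth, an arithmetic midparent, the fit without both run 3 libraries, and separate parental libraries for each cross were added. The planned negative binomial count tests were not run, because the files hold RPKM. The count of called features was also taken over 100 splits of the libraries into groups of the same sizes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.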

Results

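RNA abundance was measured in 9 libraries of Tigriopus californicus, a small crustacean of rocky splash pools whose coastal populations have diverged strongly. Libraries came from San Diego animals (SD, n = 3), Santa Cruz animals (SCN, n = 2), hybrids with SD mothers (SDf x SCNm, n = 2) and hybrids with SCN mothers (SCNf x SDm, n = 2). Mitochondria pass through the mother, so both crosses carry mixed nuclear genomes on different mitochondrial genomes. Recovered reads numbered 14.9 M, 4.74 M and 0.832 M in SD replicates 1, 2 and 3, and 3.27 M and 1.32 M in SCN replicates 1 and 2. They numbered 4.2 M and 12.7 M in SDf x SCNm replicates 1 and 2, and 11.8 M and 10.8 M in SCNf x SDm replicates 1 and 2. SD replicate 3 and SCN replicate 2, sequenced together in run 3, had 0 reads in 7.51% and 8.17% of features, against 0.0219% to 0.672% in the other libraries.

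The first principal component, with 42.1% of the variance, placed SCN replicate 2 at -116, SD replicate 3 at -39.4, SD replicate 1 at -2.92 and the other 6 libraries between 12.2 and 48.5. The second, with 26.1%, parted the SD libraries (42.1 to 58.8) from all others (-44.4 to -9.25). Mitochondrial genes took 2.62% to 7.48% of summed RPKM in SD, 7.24% and 9.81% in SCN, and 4.74% to 7.88% in hybrids. No replicate pair agreed within sampling noise, with a chi-square per feature of 10.3 to 66.3. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

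**Figure D1:**
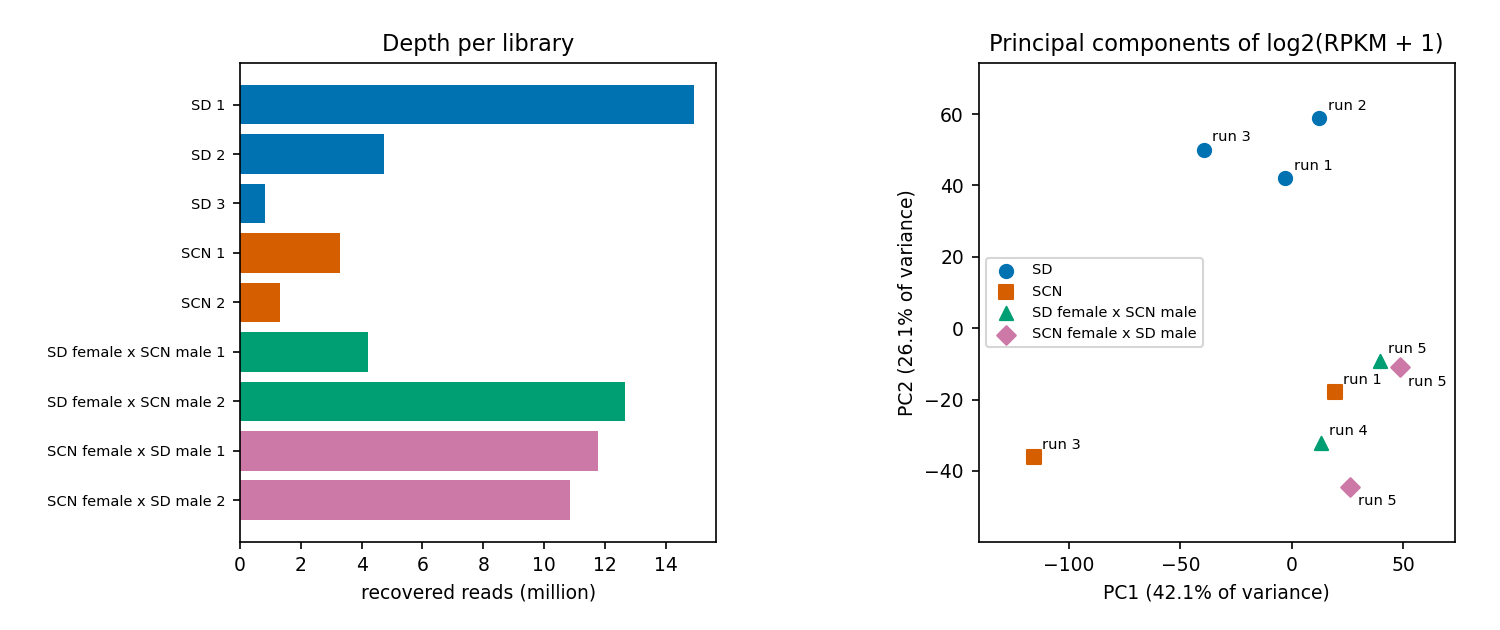
Recovered reads (M) per library (bars, left) and the first and second principal components of log2(RPKM + 1) over all features, with each library's sequencing run (right). SD replicate 3 (0.832 M reads) and SCN replicate 2 (1.32 M), both from run 3, have the lowest values on the first component.

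The parental populations were compared first. Pyridine nucleotide-disulfide oxidoreductase domain-containing protein 2 (Contig4724) was lower in SD, at 12.6 ± 4.79 RPKM (s.d., n = 3) against 421 ± 157 in SCN (n = 2), a 31.0-fold difference (log2 -4.95, SE 0.39, limma adjusted p = 9.57e-04). A ubiquitin contig (Contig1785), which encodes the tag that marks proteins for the proteasome, was 13.7-fold lower in SD, at 55.9 ± 16.4 against 771 ± 184 RPKM (adjusted p = 0.00197). A chymotrypsin-like protease (Contig1226cap), of a family of digestive enzymes, was 16.0-fold higher in SD, at 193 ± 122 against 10.3 ± 5.25 RPKM (adjusted p = 0.0146). A cytochrome P450 (Contig5704), of a family of detoxifying and steroid-processing oxidases, was 22.0-fold higher in SD, at 286 ± 215 against 8.07 ± 1.55 RPKM (adjusted p = 0.0491). Heat shock factor (Contig993), the transcription factor that turns on heat shock genes, stood at 277 ± 47.1 RPKM in SD against 69.0 ± 2.32 in SCN (adjusted p = 0.0405).

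Others higher in SD were an aminopeptidase N-like protein (Contig69cap, log2 3.56), an SH3 domain-binding protein 5-like protein (Contig5527, 3.06), nanos homolog 2 (Contig4701, 3.04), which represses translation in germ cells, short stature homeobox (Contig19699, 2.50) and a zinc finger rad18 domain-containing protein (Contig1664, 2.11). Others lower in SD were a retrotransposon-like contig (Contig23597, log2 -2.98), an exosome component mtr3-like protein (Contig24202, -2.31), GTP cyclohydrolase I (Contig4801, -2.25), the first enzyme of pterin synthesis, and the metalloproteinase nas-13-like (Contig2534, -2.07). A pyridoxine biosynthesis protein (Contig22998, log2 -3.32) and Contig15713 (-1.95) did not pass, each with an adjusted p of 0.0539. Unnamed contigs held the largest differences of all: Contig3123cap stood at 1332 ± 718 RPKM in SD against 9.64 ± 4.52 in SCN (log2 6.88), Contig3677cap differed by 6.10 and Contig42697 by -5.38. Contig12698 (-4.79), also unnamed, came after Contig4724. Within runs 1 and 3, SD minus SCN was -4.92 and -5.53 for Contig4724, -4.20 and -3.08 for the ubiquitin contig, 4.37 and 2.68 for the chymotrypsin-like protease and 5.86 and 5.11 for the P450. Contig4724, the ubiquitin contig, Contig3123cap, Contig3677cap and Contig42697 passed in 22 of 22 alternative fits, the chymotrypsin-like protease in 20, the P450 in 6, heat shock factor in 8 and nanos homolog 2 in 4.

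Over all features, limma called 24 higher and 35 lower in SD, 14 of them with an informative name; 2411 had an unadjusted p under 0.05 and the median feature was 0.23 higher in SD on the log2 scale. The groups did not overlap in 3983 features, or 29.0% where chance gives 20%, including all 59 called ones. Without overlap the sign within run 1 and within run 3 must be the same, so that agreement of all 59 adds no support. Across all features the run 1 and run 3 differences had r = 0.25 and the same sign in 56.1%. Quantile normalization gave 29 higher and 66 lower, median-of-ratios scaling 17 and 57, voom 7 and 53, and the run as a block called 161 features in 5 parental libraries and 157 in the 4 libraries of runs 1 and 3. The count was 11 without SD replicate 1, 19 without SD replicate 2, 13 without SD replicate 3 and 3085 without SCN replicate 1, where the balance turned to 2490 higher and 595 lower. It was 19 without SDf x SCNm replicate 1, 22 without its replicate 2, and 19 without either SCNf x SDm library.

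Gene lists described the parental difference by group, with medians given relative to that shift of 0.23 in all features. The proteasome and ubiquitin list, the main route of protein degradation, was higher in SD (167 members, relative median 0.31, camera adjusted p = 0.00532), as was the germline list (19 members, 0.29, adjusted p = 0.0151). With an estimated correlation both had an adjusted p = 0.529, while fry, which tests against no change and so includes the shift of all features, gave 0.00376 for both. The only proteasome and ubiquitin member past the threshold over all features was the ubiquitin contig, which ran against its list; adjusted over the list alone it was joined by 2 higher in SD, the E3 ligases siah1 (Contig1903, log2 2.00) and march5 (Contig960cap, 1.48). Of the germline members nanos homolog 2 passed, and 2 did when adjusted over the list alone, the other being a synaptonemal complex protein (Contig4930, log2 1.57) of meiotic chromosomes. Within runs 1 and 3, where the median of all features was 0.02 and 0.46, the relative median was 0.35 and 0.20 for proteasome and ubiquitin. For the germline it was 0.48 and -0.02, so that list's place above other features did not hold within run 3.

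Lists lower in SD were antioxidant and glutathione genes (62 members, relative median -0.58, adjusted p = 3.08e-04), which remove reactive oxygen, glycolysis and the TCA cycle (43, -0.52, 3.08e-04) and digestive peptidases (63, -0.50, 0.0105). Nuclear complex I genes (16 members, relative median -0.37, adjusted p = 0.0267), cuticle and chitin (86, -0.33, 0.0139) and cytosolic ribosomal proteins (69, -0.36, 0.00275) were also lower, but the ribosomal median turned from -0.13 as deposited to 0.12 under quantile normalization. With an estimated correlation the adjusted p was 0.626 for the antioxidant and glycolysis lists, 0.724 for peptidases, complex I and ribosomal proteins, and 0.750 for cuticle. Over all features 0 members passed except among peptidases, with the chymotrypsin-like protease higher and nas-13-like lower. Adjusted over the list alone, 2 antioxidant genes were lower, a metaxin-like glutathione transferase (Contig995cap, log2 -2.17) and glutathione peroxidase 7 (Contig14253, -1.93), and 2 peptidases were higher and 1 lower. Within run 1 and run 3 the relative medians were -0.14 and -0.83 for antioxidant genes, -0.16 and -0.73 for glycolysis, -0.18 and -0.997 for complex I and -0.07 and -0.81 for ribosomal proteins. They were -0.81 and -0.11 for cuticle and -0.44 and -0.19 for peptidases, whose unshifted medians took opposite signs (-0.79 and 0.36, and -0.42 and 0.27).

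Library SCN replicate 2 moved with several of these lists: its list medians of log2(RPKM + 1) were 4.03 for cuticle against 5.97 in SCN replicate 1, 5.29 against 6.26 for peptidases, 10.79 against 10.18 for ribosomal proteins, and 8.64 against 11.54 for yolk genes. Without SCN replicate 2 the adjusted p was 0.119 for antioxidant genes, 0.192 for glycolysis, 0.809 for complex I and 0.350 for ribosomal proteins, and the last pair's tests then pointed up. Without SCN replicate 1 it was 0.607 for proteasome and ubiquitin, 0.338 for the germline, 0.614 for peptidases and 0.607 for cuticle, whose median became 0.83. Without SD replicate 3 it was 0.243 for cuticle and 0.0661 for complex I, and without SD replicate 1 it was 0.137 for complex I.

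No difference was called for the remaining lists. Relative medians and adjusted p were 0.56 and 0.0620 for mtDNA transcription and replication genes, -0.40 and 0.210 for complex III, -0.24 and 0.367 for complex IV, and -0.06 and 0.435 for mitochondrial ribosomal proteins. They were 0.10 and 0.788 for heat shock proteins, -0.03 and 0.468 for cytochrome P450, -0.29 and 0.1 for immune recognition, and -0.24 and 0.182 for oxygen transport. Among stage, sex and tissue markers they were 0.29 and 0.677 for yolk, 0.26 and 0.0990 for sperm and cilia, 0.26 and 0.177 for cell division, -0.19 and 0.0990 for muscle, and 0.08 and 0.788 for the nervous system. Adjusted over the list alone, 2 members of the mtDNA transcription and replication list, 2 P450s, 1 heat shock gene and 1 cell division gene were higher in SD. Lower were 1 immune and 1 cell division gene. For mitochondrial ribosomal proteins, yolk, muscle and the nervous system the unshifted median and mean lay above 0 while the test, which compares with other features, pointed down. The short complex II and complex V lists were not tested: the succinate dehydrogenase membrane subunit (Contig715cap) had log2 -1.57 and the iron-sulfur subunit (Contig4987) -0.12, and the complex V contigs had -1.52 (Contig984cap), 0.52 (Contig35439) and -0.34 (Contig9591).

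The 13 protein-coding genes of the mitochondrial genome, which encode core subunits of the respiratory chain, had lower values in SD as a list (relative median -1.19, camera adjusted p = 1.09e-04). With an estimated correlation the adjusted p = 0.626, and 12 of the 13 genes lay below 0. Cytochrome c oxidase subunit 1 (cox1) averaged 12963 ± 7943 RPKM in SD and 32971 ± 12880 in SCN (log2 -1.49, SE 0.69, adjusted p = 0.293). Cytochrome b (cytb) had log2 -1.82 (SE 0.65, adjusted p = 0.207), cox2 -1.92, nad3 -1.85, ATP8 -1.05, cox3 -1.02, nd4L -0.97, ATP6 -0.83, nad2 -0.68, nad4 -0.45, nad5 -0.40, nad6 -0.35 and nad1 0.05. None of the 13 genes passed by limma, over all features or adjusted over the list alone. The list's relative median was -0.47 within run 1 and -0.77 within run 3, its adjusted p was 0.113 with quantile normalization, and it was 0.0951 without SCN replicate 2.

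**Figure D2:**
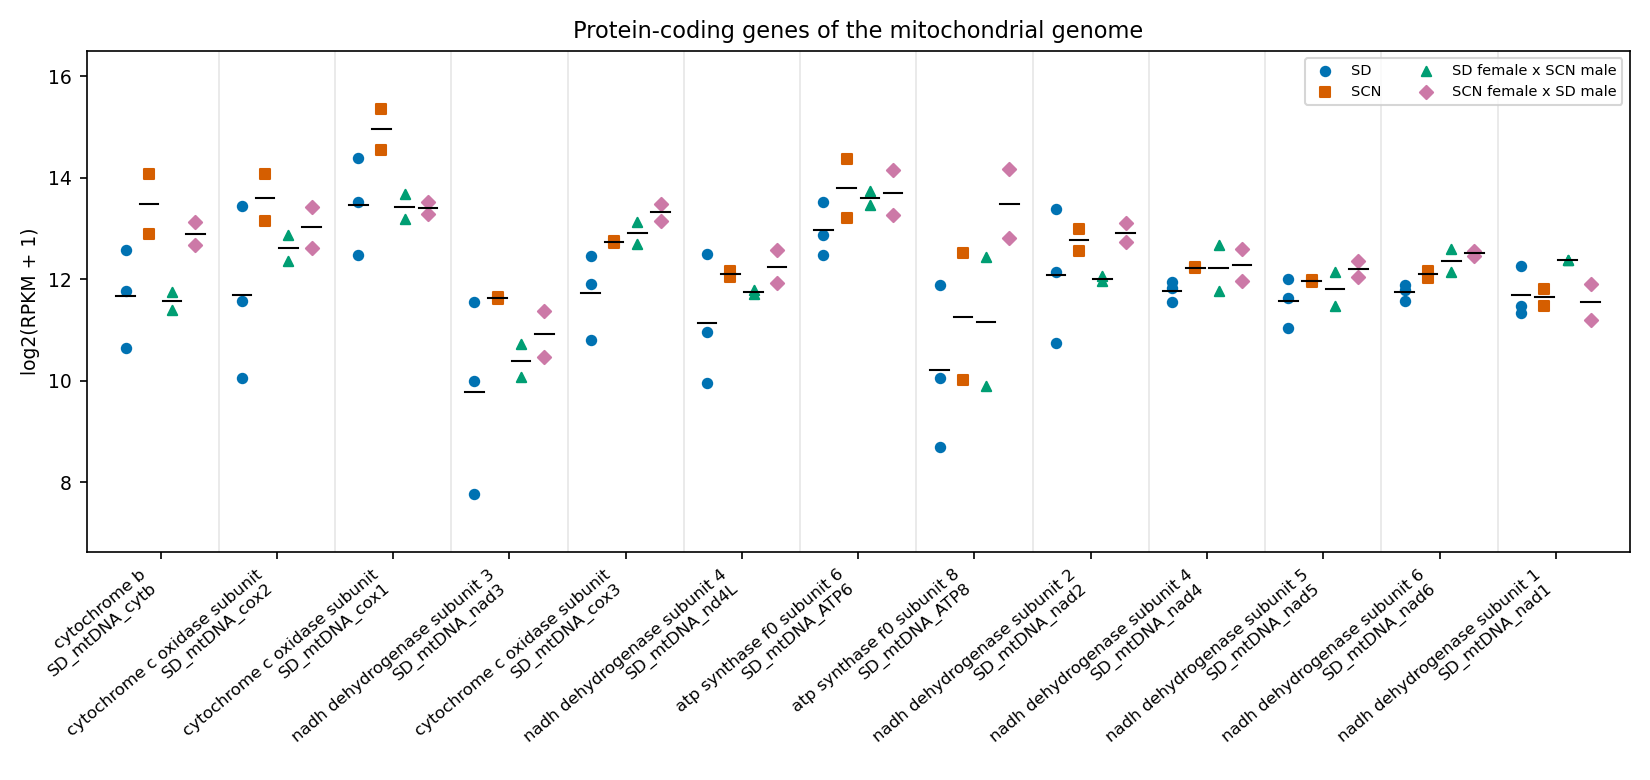
log2(RPKM + 1) of the 13 protein-coding mitochondrial genes in each of the 9 libraries (points), with group means (black bars). Cox1 averages 12963 RPKM in SD, 32971 in SCN and 11034 in hybrids, and cytb 3063 in SDf x SCNm and 7732 in SCNf x SDm; none of the 13 genes passed the test in any comparison.

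Hybrids were next set against the midparent, the mean of the SD and SCN means on the log2 scale. A C-type lectin-like precursor (Contig11276), of a family that binds sugars on microbes, rose to 441 ± 207 RPKM in hybrids (n = 4) from 47.6 ± 13.4 in SD and 68.7 ± 31.7 in SCN, 7.21-fold above the midparent (log2 2.85, SE 0.30, adjusted p = 0.0202). Genes of the chitin-based exoskeleton rose too: obstructor (Contig19526) was 9.60-fold above the midparent, at 234 ± 113 RPKM against 18.6 ± 12.4 in SD and 37.5 ± 33.4 in SCN (adjusted p = 0.0237). Chitinase-3-like protein 1 (Contig10608, log2 3.06), cuticle proteins (Contig31846, 3.01, and Contig32330, 3.01) and larval cuticle protein lcp-17 (Contig977cap, 2.77) lay with it. Glutathione S-transferases, which attach glutathione to toxins, rose to 730 ± 385 RPKM (Contig10970, log2 3.24, adjusted p = 0.0447) and 404 ± 86.5 RPKM (Contig1767cap, 2.29, adjusted p = 0.0239). Cytochrome c oxidase subunit 6c (Contig470), a nuclear subunit of complex IV, stood at 1872 ± 524 RPKM in hybrids against 521 ± 115 in SD and 388 ± 151 in SCN (log2 2.06, adjusted p = 0.0237).

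Also above the midparent were a vesicle coat complex subunit (Contig25834, log2 2.59), a C-type lectin domain family 4 member (Contig94595, 2.36), superoxide dismutase (Contig12397, 1.42), which detoxifies superoxide, ribosomal protein RpS21 (Contig62709, 2.01) and subunit 4 of the NADH dehydrogenase beta subcomplex (Contig760cap_1, 1.72), with the unnamed Contig39532 (3.49) and Contig33010 (3.35). In all 4 hybrid libraries each of these named genes lay above the midparent. For those named by largest change the naming rule required this, so it adds no support. Contig3301, unnamed and picked after its values were seen, was the only called fall (log2 -2.68, adjusted p = 0.0472). The named genes with the smallest p below the midparent did not pass: troponin I (Contig1745cap, log2 -1.59) and a lipin-like phosphatidate phosphatase (Contig1014, -1.23) had an adjusted p of 0.0562. Cytochrome c oxidase subunit 4 (Contig3271) had log2 -0.89 (adjusted p = 0.131). Of 22 alternative fits the lectin passed in 18, the smaller glutathione S-transferase change in 15, lcp-17 in 14, subunit 6c in 13, obstructor in 12, chitinase-3-like in 11, the larger glutathione S-transferase change in 7, RpS21 in 6, and superoxide dismutase and the NADH dehydrogenase subunit in 5.

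**Figure D3:**
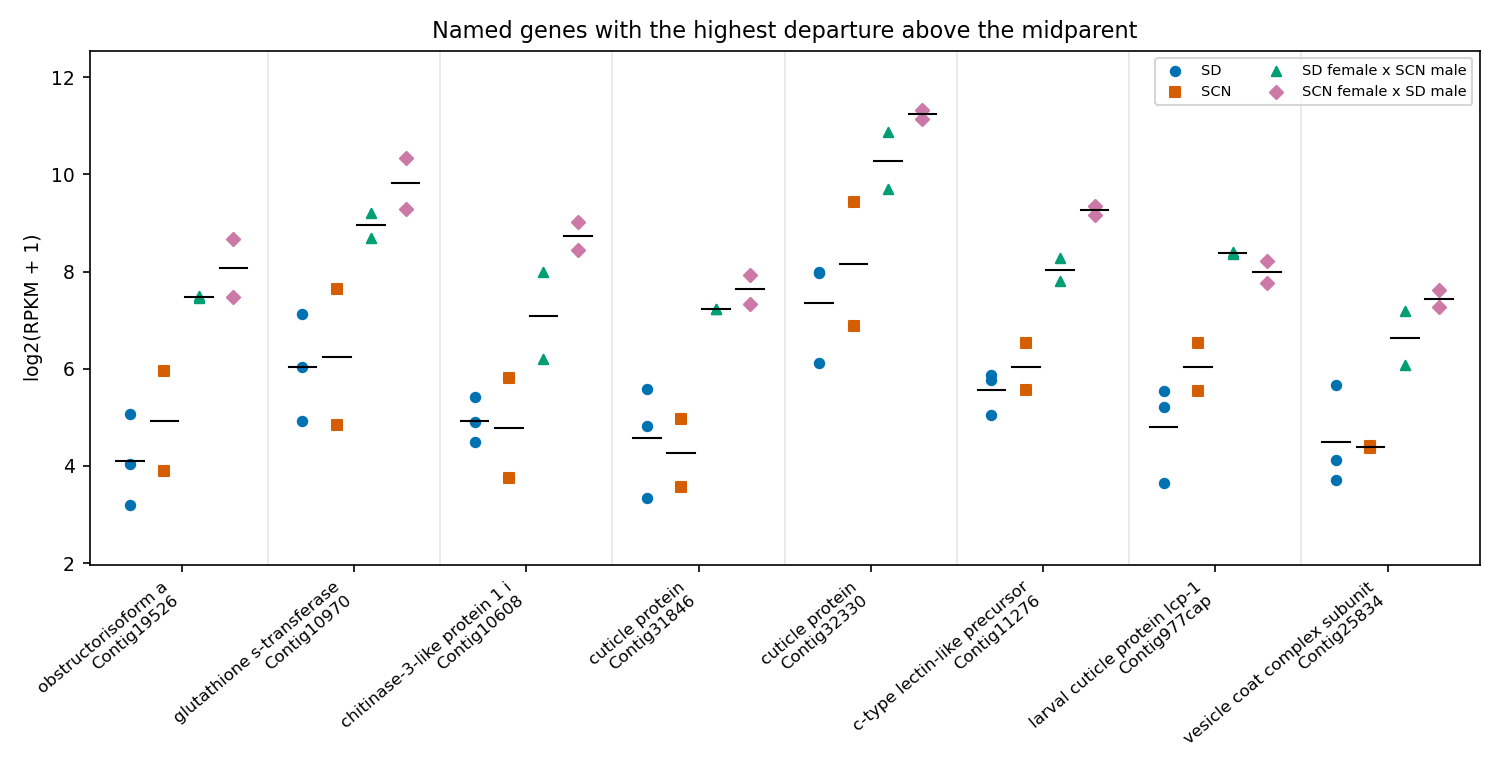
log2(RPKM + 1) of the 8 named genes with the largest change above the midparent in each of the 9 libraries (points, by group). The C-type lectin-like precursor averages 441 RPKM in hybrids, 47.6 in SD and 68.7 in SCN.

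Over all features limma called 109 above and 1 below the midparent, 37 of them with an informative name, while 2268 had an unadjusted p under 0.05 and the median feature lay 0.15 above. Hybrid and parental libraries did not overlap in 1012 features, or 7.36% where chance gives 1.59%, including 97 of the 110 called ones. No run held both hybrids and parents, so sequencing run and hybrid status cannot be told apart. The count was 0 without SD replicate 1, 33 without SD replicate 3, 2985 without SCN replicate 1 (2374 above and 611 below) and 43 without SCN replicate 2. It was 3 and 4 without SDf x SCNm replicates 1 and 2, and 0 without either SCNf x SDm replicate 1 or replicate 2. Without both run 3 libraries it was 108, all above, and 62 of these were among the 110. Other fits called 193 with a pseudocount of 5, 170 with quantile normalization, 209 with 2 groups, 56 against an arithmetic midparent, 34 with the added constant taken off and 16 at 1 depth.

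The cuticle and chitin list rose most among the lists above the midparent, with 80 of 86 members above 0 and a median 0.90 above that of all features (camera adjusted p = 5.38e-16; adjusted p = 0.490 with an estimated correlation). Of its members 9 passed over all features and 41 adjusted over the list alone. Its list median was 6.0 to 6.33 in the 4 hybrid libraries on the log2(RPKM + 1) scale, 4.62 to 5.08 in SD, 5.97 in SCN replicate 1 and 4.03 in SCN replicate 2. Immune recognition genes rose (relative median 0.46, adjusted p = 1.84e-04, and adjusted p = 0.490 with an estimated correlation), with both lectins passing and 9 members when adjusted over the list alone. Digestive peptidases (relative median 0.40, adjusted p = 0.00253) and antioxidant genes (0.21, 0.00669) rose relative to other features, with adjusted p = 0.894 and 0.728 with an estimated correlation. Peptidase list medians were 5.92 to 6.41 in hybrids and 5.49 to 5.82 in SD. SCN replicate 1 (6.26) lay within the hybrid range and SCN replicate 2 (5.29) below it. Fry, which tests against no change, called 0 lists in hybrids against the midparent (smallest adjusted p = 0.0897). Among peptidases 0 members passed, and 6 did when adjusted over the list alone, including a chymotrypsin-like proteinase (Contig1066cap, log2 1.80) and a trypsin (Contig39803, 2.61). Of the antioxidant genes 5 passed, and 11 adjusted over the list alone.

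Nuclear complex I genes (relative median 0.25, adjusted p = 0.0281) and cytosolic ribosomal proteins (0.23, 2.40e-04) rose as lists relative to other features. Each had an adjusted p = 0.894 with an estimated correlation, and fry called neither. One complex I member passed and 5 did when adjusted over the list alone, among them beta subcomplex members (Contig3176, log2 1.14, and Contig12185, 1.48). Of the ribosomal proteins RpS21 passed, and 11 did when adjusted over the list alone, including RpL37a (Contig61723, log2 1.79). Lists below the rest of the features were proteasome and ubiquitin (relative median -0.30, adjusted p = 1.67e-04), glycolysis and the TCA cycle (-0.35, 2.40e-04) and the germline (-0.42, 0.00253). With an estimated correlation their adjusted p = 0.195, 0.510 and 0.195. No member passed by limma, over all features or over the list alone; 6-phosphofructokinase (Contig9688), which commits sugar to glycolysis, had log2 -0.91, the germline helicase vasa (Contig803) -0.76 and tudor domain-containing protein 1 (Contig976cap) -0.76.

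Cuticle, immune recognition, glycolysis, proteasome and germline lists were called with any 1 library left out. Without SCN replicate 1 the adjusted p was 0.742 for complex I, 0.740 for ribosomal proteins and 0.587 for antioxidant genes. Without SDf x SCNm replicate 1 it was 0.151, 0.0626 and 0.0744 for those lists and 0.0609 for peptidases, without SCNf x SDm replicate 2 it was 0.237, 0.0954, 0.192 and 0.0595, and without SD replicate 1 it was 0.0736 for complex I.

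**Figure D4:**
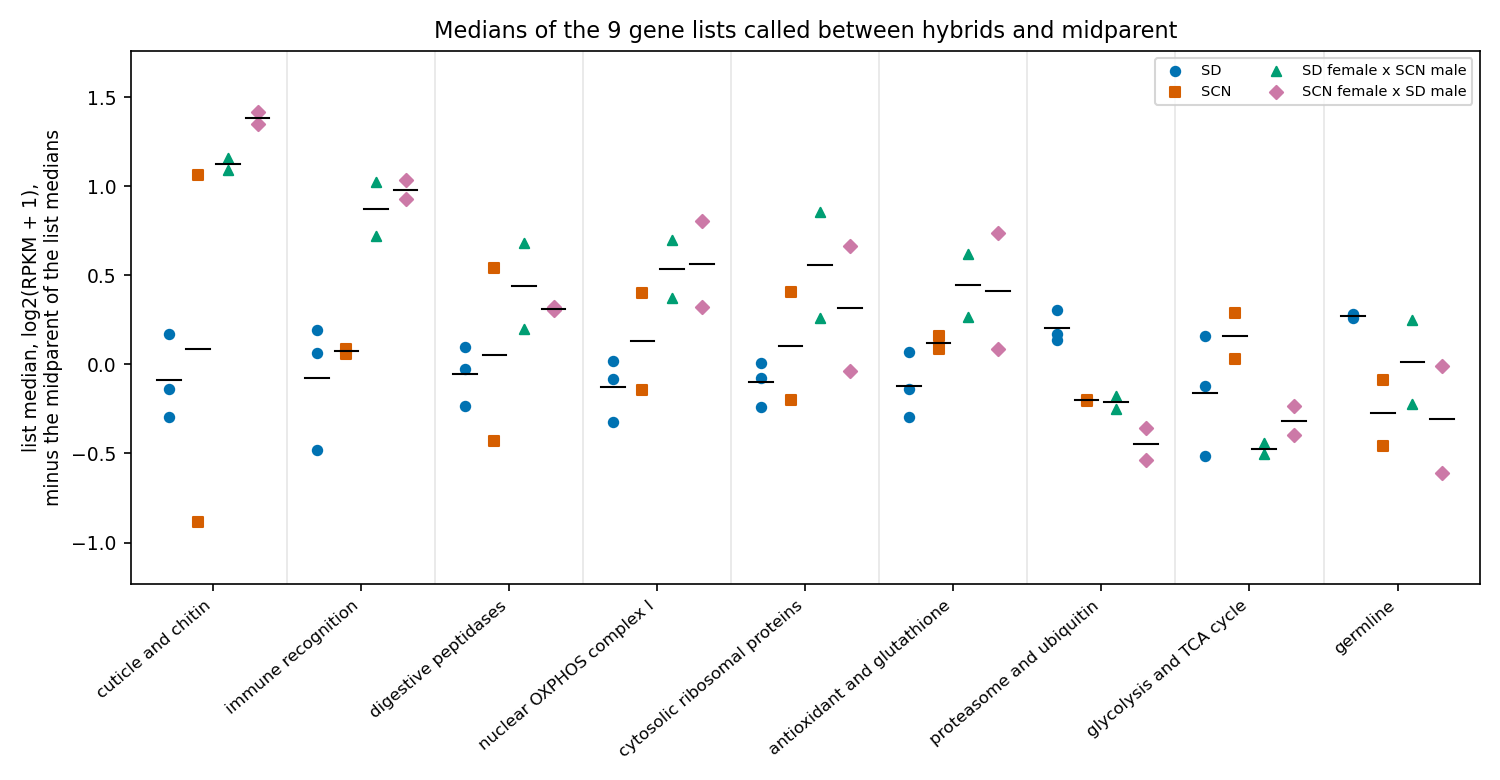
Median log2(RPKM + 1) of each of the 9 called lists per library (points), minus the mean of the SD and SCN list medians, with group means (black bars). Cuticle and chitin medians are 6.0 to 6.33 in hybrids, 4.62 to 5.08 in SD, and 5.97 and 4.03 in SCN before subtraction.

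No other list was called against the midparent. Relative medians and adjusted p were 0.10 and 0.732 for the mitochondrial genome, 0.09 and 0.692 for complex III, 0.22 and 0.451 for complex IV, 0.12 and 0.211 for mitochondrial ribosomal proteins and -0.10 and 0.904 for mtDNA transcription and replication. They were -0.06 and 0.428 for heat shock proteins, 0.21 and 0.229 for cytochrome P450 and 0.11 and 0.692 for oxygen transport. Among stage, sex and tissue markers they were 0.28 and 0.692 for yolk, -0.06 and 0.428 for cell division and -0.09 and 0.428 for the nervous system. Unshifted medians for sperm and cilia and for muscle were both 0.15, with adjusted p = 0.890 and 0.428. Adjusted over the list alone, 2 complex III genes, 1 mitochondrial ribosomal protein, 1 cell division gene and tropomyosin (Contig5890, log2 1.248) lay above, 2 complex IV genes above and subunit 4 below, and troponin I below. Heat shock, mtDNA transcription, sperm, cell division, muscle and nervous system lists had an unshifted median and mean above 0 and a test pointing down. Complex II contigs had log2 0.33 (Contig715cap) and 0.12 (Contig4987), and complex V contigs 1.03 (Contig35439), -0.02 (Contig984cap) and 0.00 (Contig9591).

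None of the 13 mitochondrial genes passed in hybrids against the midparent. Mitochondria pass through the mother, so for these genes the midparent is a yardstick for both crosses together, not for either alone. The log2 values were 1.59 for ATP8, 0.89 for cox3 (adjusted p = 0.337), 0.51 for nad6, 0.38 for nd4L, 0.30 for nad1, 0.27 for ATP6, 0.25 for nad4, 0.24 for nad5, 0.18 for cox2, 0.03 for nad2, -0.04 for nad3, -0.34 for cytb and -0.79 for cox1. Cox1 averaged 11034 ± 1716 RPKM in hybrids (n = 4), and 4 of 4 hybrid libraries lay below its midparent.

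Against each parent separately, hybrids were 209 features above and 11 below SD, 85 with an informative name, and 2 above SCN. Both features above SCN were unnamed contigs that also separated the parents: Contig3123cap was 7.44 above SCN on the log2 scale (adjusted p = 0.00115), at 1896 ± 834 RPKM, and Contig3677cap was 4.47 above (adjusted p = 0.0108), at 204 ± 15.4 RPKM. Unadjusted p lay under 0.05 for 2628 features against SD and 2100 against SCN, and the median feature differed by 0.02 and 0.29. Quantile normalization gave 426 above and 112 below SD, median-of-ratios scaling 318 and 20, and voom 495 and 69. Without both run 3 libraries 648 lay above and 76 below SD.

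By list, hybrids lay above SD in cuticle (median 1.28, camera adjusted p = 3.67e-15), immune, antioxidant, complex I, ribosomal, peptidase and mitochondrial genome genes, and below it in proteasome (-0.39) and germline (-0.61) genes. None of these 9 lists was called once the correlation was estimated (0 of 9), with an adjusted p from 0.0932 (proteasome and germline) to 0.707 (mitochondrial genome). Fry called 5 lists, the antioxidant, proteasome, immune and germline lists among these and oxygen transport (median 0.39). Quantile normalization took the ribosomal median from 0.54 to 0.05 and that of the mitochondrial genome from 0.69 to 0.14. Against SCN, cuticle (median 1.18, adjusted p = 3.65e-08) and immune genes lay above and glycolysis below (-0.54, 4.95e-08), with a smallest adjusted p = 0.901 with an estimated correlation. The cuticle list median was 5.97 in SCN replicate 1 and 4.03 in SCN replicate 2, against 6.0 to 6.33 in hybrids. The cuticle gap to SCN therefore rests mostly on SCN replicate 2. Immune medians were 5.59 and 5.56 in SCN against 6.22 to 6.54 in hybrids, and glycolysis medians 6.29 and 6.55 against 5.76 to 6.03.

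The count against SD was 41, 71 and 40 without SD replicates 1, 2 and 3, 1321 without SCN replicate 1 and 1322 without SCN replicate 2. It was 29 and 37 without SDf x SCNm replicates 1 and 2 and 40 and 15 without SCNf x SDm replicates 1 and 2. The count against SCN was 3959 without SCN replicate 1, 0 without SCN replicate 2, and 1 without SDf x SCNm replicate 2 or either SCNf x SDm library. Limma found 0 transgressive features, as did voom. A transgressive call needs a call against SCN, of which limma had 2 and voom 0, so these counts could hardly exceed 0. They do not show that no feature lay beyond both parents. All 4 hybrid libraries lay above all 5 parental ones in 806 features and below them in 206. Together these are 7.36% of features, where chance gives 1.59%. Of 253 features called in any of these comparisons, 220 were SCN-like, differing from SD and not called against SCN, of which 26 had a called difference between the parents, 2 were SD-like, and 31 differed between the parents with hybrids called against neither. SCN-like features were not shown to match SCN, since SCN replicate 1 alone moved the count against SCN so far.

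On an axis where SCN is 0 and SD is 1, with the direction taken from the parents of run 1 or run 3 and the endpoints from those of the other run, hybrids averaged -0.44 ± 0.39 (s.d., n = 4). Single libraries lay at -0.63 and -0.13 (SDf x SCNm) and -0.10 and -0.91 (SCNf x SDm), and along single axes between -1.12 and 0.65. No test of this index was planned, and none was made.

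Each cross was also set against the midparent by itself. In SCNf x SDm the C-type lectin-like precursor (Contig11276) was the single called feature, 3.46 above the midparent on the log2 scale (adjusted p = 0.0389), at 615 ± 54.1 RPKM (n = 2). In SDf x SCNm, where it stood at 266 ± 61.7 RPKM (n = 2), limma called 0 features, with 1127 at an unadjusted p under 0.05, against 1750 in SCNf x SDm; voom called 0 and 74. By list, cuticle genes rose in both crosses, with medians of 1.1 in SDf x SCNm (camera adjusted p = 9.71e-13) and 1.47 in SCNf x SDm (6.35e-18), and an adjusted p = 0.525 and 0.418 with an estimated correlation. Camera called 11 lists in SDf x SCNm and 9 in SCNf x SDm, all 9 of the latter among those called for hybrids together. With an estimated correlation 0 lists were called in either cross (smallest adjusted p = 0.525 in SDf x SCNm and 0.116 in SCNf x SDm), and fry called 0. The ribosomal list of SCNf x SDm turned from 0.26 to -0.04 under quantile normalization, and the muscle list of SDf x SCNm had a median of 0.05 and a test pointing down.

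Without SCN replicate 1 the counts were 905 and 1981, and without both run 3 libraries 0 and 90. Without any other single library SDf x SCNm had 0. SCNf x SDm had 0 without any SD library or either of its own, and 2 without SCN replicate 2 or SDf x SCNm replicate 2. The departures of both crosses from the midparent had r = 0.87 across features and the same sign in 83.6%. Unchanged groups simulated against the same parents gave r = 0.30 and 59.6%. The SCN libraries, whose noise enters both departures, differed more from each other than other replicates did. The median residual s.d. of 0.48 fell to 0.37 and 0.36 without SCN replicates 1 and 2. Simulated values for shared parents may therefore be too low, and the gap to them overstated. The covariance was 0.338 against 0.060 simulated. Without SDf x SCNm replicate 2, so that the crosses shared no run, r was 0.67 against 0.23 simulated, with a covariance of 0.301. With separate parents, the run 1 pair for SDf x SCNm and the run 3 pair for SCNf x SDm, r was 0.43 with the same sign in 59.2%, and with these exchanged 0.51 and 62.1%, where simulated unchanged groups gave r near 0 and 49.9% and 50.1%. With SDf x SCNm replicate 1 alone, so that neither parents nor runs were shared, r was 0.22 and 0.48, with the same sign in 52.3% and 62.0%. Features are not independent replicates, so no p-value is given.

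The reciprocal crosses, assigned by title, were compared for differences that go with the mother's population. The source label of both SCNf x SDm libraries names the opposite cross, so this assignment is uncertain. Hybrid libraries did not group by cross. Pearson r of log2 values was 0.940 within SDf x SCNm and 0.956 within SCNf x SDm. Between the crosses it was 0.924, 0.957, 0.958 and 0.981. Cytochrome b averaged 3063 ± 522 RPKM in SDf x SCNm and 7732 ± 1672 in SCNf x SDm (n = 2 each, log2 -1.33, SE 0.71). The C-type lectin-like precursor had log2 -1.22 (SE 0.45), a glucosyl/glucuronosyl transferase (Contig18473) -2.26 (SE 0.62), timeless (Contig3957), a circadian clock protein, -1.54, torso-like (Contig308) -1.24 and heat shock protein beta-1 (Contig753cap) -0.87. On the other side lay an AMP-dependent CoA contig (Contig18737, 1.252, SE 0.37), sperm autoantigenic protein 17-like (Contig3088cap, 1.52) and the transcription factor kayak (Contig3278, 0.86). The other mitochondrial genes had log2 -2.33 (ATP8), -0.91 (nad2), -0.52 (nad3), -0.50 (nd4L), -0.41 (cox3), -0.40 (cox2), -0.39 (nad5), -0.14 (nad6), -0.11 (ATP6), -0.05 (nad4), 0.03 (cox1) and 0.83 (nad1).

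None of these passed: limma called 0 features, with 39 at an unadjusted p under 0.05 and every adjusted p at or near 0.9999, and voom called 0. The groups did not overlap in 28.7% of features where chance gives 33.3%. The median feature differed by 0.05. Within run 5, where SDf x SCNm replicate 2 ran beside both SCNf x SDm libraries, cytochrome b had log2 -1.50, the lectin precursor -1.46, the glucosyl/glucuronosyl transferase -1.74 and the AMP-dependent CoA contig 0.97.

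Camera nevertheless called 12 lists between the crosses, with 0 members passing in any of them, over all features or adjusted over the list alone. Lower in SDf x SCNm were cuticle (median -0.33, adjusted p = 4.34e-07), the mitochondrial genome (-0.40, 0.00137), muscle (-0.17, 7.34e-04), oxygen transport (-0.33, 0.00387), cytochrome P450 (-0.14, 0.00447), immune recognition (-0.14, 0.00853) and the nervous system (-0.11, 0.0319). Higher were proteasome and ubiquitin (0.21, 1.60e-04), germline (0.30, 5.06e-04), cell division (0.27, 6.06e-04), cytosolic ribosomal proteins (0.22, 0.00113) and mtDNA transcription and replication (0.33, 0.0366). With an estimated correlation the adjusted p was 0.154 for proteasome, germline and oxygen transport, 0.431 for cell division and 0.744 to 0.833 for the rest, and fry called 0 lists. Within run 5, relative to its all-feature median of 0.05, the medians were -0.24 for cuticle, -0.25 for the mitochondrial genome, 0.11 for proteasome and ubiquitin, 0.30 for the germline and 0.26 for cell division. The ribosomal list (-0.08) did not keep its direction there. The ribosomal list turned to -0.03 without SDf x SCNm replicate 1 and to -0.10 without SCNf x SDm replicate 1. Cuticle, proteasome, germline and cell division lists were called with any 1 library left out; cell division reached an adjusted p of 0.0499 at most. Calls were lost for the mitochondrial genome (adjusted p = 0.776), immune recognition (0.659), P450 (0.320) and oxygen transport (0.102) without SCNf x SDm replicate 2, for mtDNA transcription without SDf x SCNm replicate 2 (0.304) or SCNf x SDm replicate 1 (0.269), and for muscle (0.0993) and the nervous system (0.513) without SCNf x SDm replicate 1. Without SDf x SCNm replicate 1 they were lost for P450 (0.3296) and the nervous system (0.327), and without its replicate 2 for immune recognition (0.289) and the nervous system (0.0527).

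Uncalled between the crosses were complex I (median -0.12, adjusted p = 0.291), complex III (-0.03, 0.499), complex IV (-0.17, 0.291), mitochondrial ribosomal proteins (0.10, 0.0836), heat shock proteins (-0.01, 0.721), antioxidant genes (-0.02, 0.670), glycolysis (-0.03, 0.499), yolk (0.06, 0.721) and sperm and cilia (0.09, 0.279). Digestive peptidases had a median of 0.05 and a test pointing down (0.818).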

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

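The results below were picked because both libraries of SDf x SCNm lay on one side of the midparent and both libraries of SCNf x SDm on the other; whether the crosses differ in this way was not tested, and limma called 0 features between them. Cytochrome b had departures of -1.0 in SDf x SCNm and 0.33 in SCNf x SDm, a difference of -1.33, and nad2 had -0.42 and 0.49, a difference of -0.91. Both genes are encoded by the mitochondrial genome, which each cross takes from its mother. If each cross kept its mother's level, the midparent would not be the value to expect. SD lay below SCN for both genes, without a call, so this split has the direction of the mothers' difference. However, 12 of the 13 mitochondrial genes lay lower in SD, so a gene lower in SDf x SCNm would mostly share that direction. Cox1, cox2 and nad3 had larger parental differences than nad2 and were not picked. The source labels also leave the assignment of the crosses uncertain. The zinc finger protein c3h1 type-like (Contig49) had -0.40 and 1.00 (difference -1.41), the AMP-dependent CoA contig (Contig18737) 0.41 and -0.85 (1.252), and the transcription factor kayak (Contig3278) 0.55 and -0.32 (0.86).

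Among gene lists, summarized by the median per library, oxygen transport had departures of -0.23 in SDf x SCNm and 0.58 in SCNf x SDm, a difference of -0.81. The mtDNA transcription and replication list had 0.17 and -0.16 (0.33), cell division and histones 0.08 and -0.21 (0.29), and complex V -0.02 and 0.15 (-0.17). With 2 libraries on each side such a split is common by chance, and whether it was more common here was not tested.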

How the results depend on the processing

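The voom, added-constant, 1-depth, arithmetic-midparent, separate-parent, separate-run and no-run-3 fits were chosen after the data were seen. Cytosolic ribosomal proteins in SD against SCN turned from -0.13 to 0.12 with quantile normalization (adjusted p = 0.751), 0.10 without both run 3 libraries (0.582) and 0.15 without SCN replicate 2 (0.350), and complex I from -0.14 to 0.0758 (0.780) and 0.0222 (0.809) in the last pair of fits. Their lowest values with a library left out were -0.36 and -0.40, both without SCN replicate 1. Cuticle in SD against SCN turned to 0.83 without SCN replicate 1 (0.607; lowest value -1.18 without SCN replicate 2), and ribosomal proteins between the crosses to -0.03 and -0.10 without SDf x SCNm replicate 1 (0.148) and SCNf x SDm replicate 1 (0.00319; highest value 0.53 without SCNf x SDm replicate 2). The cause was not tested for these or for the counts that follow. Over all alternatives, 129 of 221 counts and summary values stayed within their limit and 92 did not; of 420 list values 309 were unchanged in call and direction, 103 lost the call and 8 turned; of 6653 values of named features 6137, 366 and 150 were unchanged, lost and gained.

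For SD against SCN (59 calls) quantile normalization gave 95, array weights 6, the replicate number as a block 10, 1 depth 29, and the run as a block 161 in 5 libraries and 157 in 4. For hybrids against the midparent (110) a pseudocount of 5 gave 193, quantile normalization 170, the replicate block 55, the constant taken off 34, 1 depth 16, 2 groups 209 and an arithmetic midparent 56. For hybrids against SD (220) quantile normalization gave 538, median-of-ratios scaling 338, array weights 4592 (their estimate did not converge), the replicate block 31, voom 564, the constant taken off 132, 1 depth 98 and the fit without both run 3 libraries 724. For hybrids against SCN (2) array weights, voom and the fit without both run 3 libraries gave 0 and the constant taken off 8. SCNf x SDm against the midparent (1) had 60 with a pseudocount of 5, 57 with quantile normalization, 31 with median-of-ratios scaling, 133 with array weights, 0 with the replicate block or the constant taken off, 74 with voom, 4 at 1 depth and 90 without both run 3 libraries, and SDf x SCNm (0) had 2 at 1 depth. Called lists in SD against SCN (9) numbered 0 with an estimated correlation, 2 with fry and 4 with quantile normalization; in hybrids against the midparent (9) 0, 0 with fry and 15 without both run 3 libraries; between the crosses (12) 0 and 0. With quantile normalization 1 feature was intermediate, 1 SD-like and 537 SCN-like. On the deposited scale the crosses' departures had r = 0.67 where they shared no run, and 0.43 and 0.51 against separate parents.

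Leaving out single libraries gave 11 to 3085 calls for SD against SCN, 0 to 2985 for hybrids against the midparent, 15 to 1322 against SD, 0 to 3959 against SCN, 0 to 905 for SDf x SCNm, 0 to 1981 for SCNf x SDm, 0 to 0 between the crosses and 0 to 632 transgressive. Called lists ranged from 7 to 10, 5 to 13 and 10 to 14 in the 3 main comparisons, and r was 0.87 without SDf x SCNm replicate 1. A lone library left in a group is assumed to vary like the other groups. Without SCN replicate 1 or 2 the median residual s.d. fell alike, from 0.48 to 0.37 and 0.36, and the count against SD was 1321 and 1322. The counts of the other comparisons were high only without SCN replicate 1, as with 3085 against 60 for SD against SCN, so lower spread alone does not account for them. Deviations of samples with the same number correlated at 0.23 for SD and SCN replicates 1 (which shared run 1), -0.18 for their replicates 2, -0.55 for replicates 1 of the crosses, and 0.11 and 0.34 for SD with SDf x SCNm replicates 1 and 2. SD replicate 3 and SCN replicate 2, which shared run 3, gave 0.32. Signs differ, so the numbers were not taken to pair samples. The filter removed 0 features, so the fit without it is the same fit, and the planned count tests were not run. Depth limits SD replicate 3 (0.832 M reads) and SCN replicate 2 (1.32 M) most, with 7.51% and 8.17% of features at 0 reads.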

Other observations

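The lists of all nuclear OXPHOS genes, F-type ATP synthase and V-type ATPase, with the genes picked by symbol, were chosen after the data were seen, as were the fits at 1 depth, by voom, with the constant taken off, with an arithmetic midparent and without both run 3 libraries, the share above under quantile normalization (a planned fit), the size of the change at 1 depth, and the chi-square tests of the run 3 libraries. Nuclear OXPHOS genes of complexes I to V (42 members) had a median of -0.30 in SD against SCN (camera p = 3.28e-05, or 0.269 with an estimated correlation) and 0.29 in hybrids against the midparent (0.115, or 0.657 with an estimated correlation). F-type ATP synthase, which makes ATP in mitochondria, had 8 of 8 genes below 0 in SD against SCN, with a median of -0.46 (p = 0.00238, or 0.1601 with an estimated correlation), and a median of 0.13 in hybrids (p = 0.627). V-type ATPase, the proton pump of acidic organelles, had medians of -0.27 (p = 0.0212, or 0.138 with an estimated correlation) and 0.05 (p = 0.145). Within runs 1 and 3 the SD minus SCN medians relative to all features were -0.12 and -1.06 for nuclear OXPHOS genes, -0.22 and -1.197 for F-type ATP synthase, and -0.16 and -0.36 for V-type ATPase.

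Mitochondrial RNA polymerase (MTRPOL), which transcribes the mitochondrial genome, averaged 39.02 ± 3.59 RPKM in SD (n = 3), 14.9 ± 7.02 in SCN (n = 2) and 22.2 ± 3.70 in hybrids (n = 4). Its log2 difference was 1.40 in SD against SCN (SE 0.38, limma adjusted p = 0.132) and -0.09 in hybrids against the midparent. The mitochondrial transcription factor TFAM averaged 41.4 ± 12.5 RPKM in SD, 34.7 ± 12.8 in SCN and 70.6 ± 15.4 in hybrids (log2 0.90 against the midparent, SE 0.29, adjusted p = 0.170), and TFB1 had 0.52 in SD against SCN and -0.19 in hybrids. The yolk protein vitellogenin (Contig1764cap) averaged 4162 ± 466 RPKM in SD, 4853 ± 4670 in SCN and 8304 ± 1694 in hybrids, with a log2 difference of 1.09 from the midparent (SE 0.50, adjusted p = 0.311).

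Of the 110 features called between hybrids and the midparent 109 lay above it. Among those with informative names the largest changes were in cuticle and chitin genes, a glutathione S-transferase and the C-type lectin-like precursor. Several unnamed contigs changed more. The share above was 90.6% with quantile normalization, 98.2% against an arithmetic midparent, 100% with the added constant taken off and 100% without both run 3 libraries, so none of these choices accounts for it; it was 79.5% without SCN replicate 1 (2374 above, 611 below). At 1 depth the median of the features called above went from 2.09 to 2.61 (lower quartile 2.02), so it did not shrink. Those values also lack the added constant, and taking the constant off alone gave 2.48. Thinning keeps expected values, and these features were chosen beforehand, so it cannot exclude that depth contributed to their change. At 1 depth 16 features were past the threshold, 15 of them among the 110 and 100% above, too few to judge the share by. Voom on recovered reads called 143, 138 of them above. With the uncalled cuticle genes as a covariate the median of the called features went from 2.09 to 1.45 and 0 of 109 stayed past the threshold. The median SE rose from 0.346 to 0.462, and the cuticle list is itself higher in hybrids. The lost calls therefore cannot decide, and more cuticle-forming tissue or stages in the hybrid pools remains open. Sequencing run remains open too, because 0 runs held both parents and hybrids. How reads of each library were aligned is not given, and whether it contributed was not tested. Hybrid ancestry may be the cause only as far as none of these is.

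Random splits of the libraries gave as many calls as the real grouping in 2 of 100 cases for hybrids against the midparent, the real one included (110, highest other 249), and in 2 of 100 for hybrids against SD (220, highest other 235). Both counts of splits lie under the limit of 5 set beforehand for chance. Splits that mix populations and runs within groups can widen the spread within groups, which by itself lowers their calls. They therefore cannot exclude chance. In both cases the other split sets the 4 libraries of runs 1 and 3 apart from SD replicate 2 and the hybrids. It is nearly the real division of parents and hybrids, with only SD replicate 2 moved. Its calls are therefore not independent of the real ones, and run and hybrid status cannot be told apart in it.

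SD replicate 3 and SCN replicate 2, both of run 3, lie lowest on the first component, SCN replicate 2 by far. By correlation SD replicate 3 was not an outlier. Its Pearson r was 0.936 with SD replicate 1, the highest of the SD pairs, and 0.864 with SCN replicate 2. For SD replicate 3 low depth stays open: thinned to its depth, SD replicates 1 and 2 correlated at 0.839, which lies below the 0.854 of replicates 1 and 3 (a gap of -0.0148) and above the 0.792 of replicates 2 and 3. The chi-square per feature of replicates 2 and 3 at 1 depth was 1.58 times the highest of the within-group pairs outside run 3, and that of replicates 1 and 3 was 0.633 times. Low depth does not account for SCN replicate 2, whose chi-square per feature against SCN replicate 1 at 1 depth was 3.28 times the highest of the within-group pairs outside run 3. A few features taking most reads do not account for the pair, which stayed apart by 0.186 of the range with the 100 highest features left out, and no biological explanation was tested.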
